A study of Mus musculus with 3 samples.

How the data were processed

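Single-nucleus RNA sequencing was done on mouse heart tissue taken 2 weeks after surgery. Per the labels' protocols, nuclei were released with a detergent buffer, purified on an iodixanol cushion and made into Chromium 3' v3.1 libraries. There were 3 libraries, 1 for each group: sham surgery with NS (Sham-NS), myocardial infarction with NS (MI-NS) and myocardial infarction with dapagliflozin (MI-DAPA). The labels do not expand NS. The authors deposited matrices of UMI counts, in which each value is the number of distinct RNA molecules of a gene in a barcode. Per the file headers these were made with Cell Ranger 6.0.1. Per the submitters' processing notes the genome build was mm10 and Seurat was used, but its role is not stated. The reference release and the use of intronic reads are not stated either. Every deposited barcode had at least 500 UMIs, and the feature list held 32285 genes.

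Nuclei were kept with at least 300 detected genes and at most 10% mitochondrial UMIs. Doublets were sought per library with Scrublet in scanpy 1.11.5 at default settings, which called 0 doublets in each library, so that no nucleus was removed by it. After the scores had been seen, clusters with a median doublet score over 0.1 were left out as mixed (16.8% of Sham-NS, 12.8% of MI-NS and 11.5% of MI-DAPA nuclei). Counts per 10000 UMIs were log-transformed, 2000 variable genes were chosen per library and combined, and 30 principal components with 15 neighbours gave Leiden clusters (leidenalg 0.10.2, resolution 1.0, no batch correction). Clusters were named from 21 fixed marker sets and are written as "-like". A name also required 3 markers at least 2-fold above the other nuclei, a condition set after haemoglobin UMIs had been seen in every cluster. Vcan and Fn1, fixed both as monocyte markers and as fibroblast matrix genes, were not counted against fibroblast clusters. Macrophage-like nuclei were clustered again with 20 components at resolution 0.8.

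UMIs were summed per library and class and divided by the total UMIs of the class, on the CPM scale. Each contrast was the log2 ratio of CPM with 0.5 UMI added to each sum. With 1 library per group there was no test, and no p-value or standard error is given. Brackets give 95% intervals: exact Poisson for levels, exact conditional binomial for ratios, Clopper-Pearson for shares, and the spread of 1000 Poisson draws for list medians. These intervals cover counting error only, not differences between animals or pieces of tissue. A gene was measurable with at least 50 UMIs over both libraries of a contrast. For a gene with 0 UMIs in a library, a bound was computed from a floor of 3 counts per library and class.

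There were 32 gene lists, fixed with the markers, the comparisons and the alternatives before the data were examined. In cardiomyocyte-like nuclei they covered stress and fetal genes, adult sarcomere, fatty acid oxidation, ketone metabolism, glycolysis and glucose uptake, oxidative phosphorylation, calcium handling, sodium and hydrogen transport, and potassium channels. In fibroblast-like nuclei they covered fibrillar collagen and matrix, activated fibroblast and myofibroblast, matrifibrocyte, quiescent fibroblast, and TGF-beta pathway. The macrophage lists were resident macrophage, inflammatory cytokines and chemokines, inflammasome and NF-kB, interferon response, class II antigen presentation, lipid-associated Trem2 programme, alternative activation, and complement and phagocytosis. The endothelial lists were capillary, arterial and venous, endothelial activation, and angiogenesis. Cell cycle, immediate early and heat shock, unfolded protein and oxidative stress, haemoglobin, mitochondrially encoded and sex-linked genes were read in every class. Each list with at least 5 measurable members was given as its median log2 ratio and as a percentile among 10000 random lists matched on mean level. Lists with fewer, among them haemoglobin and cell cycle genes, have a median without a percentile. The percentile describes these libraries and is not a p-value.

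Named genes followed a fixed rule. In each of 4 classes and both main contrasts it took the 3 highest and 3 lowest ratios among eligible genes that differed at least 2-fold, up to 4 eligible members of each list, and 12 genes whatever their level, among them Slc5a2, Slc5a1 and Nlrp3. Eligible genes were measurable, had UMIs in at least 10 nuclei of the class in the higher library, and lay at or above the level of all other nuclei there, as a guard against free RNA. Predicted, mitochondrial, ribosomal, haemoglobin, immunoglobulin variable and sex-linked genes were not eligible. The text gives examples from the genes so named, and 2 of them are not reported here and were left out of the sensitivity counts. Levels of Ccr2, Trem2, Eif2s3y and Uty, the UMIs of Xist, Slc34a1 and Lrp2, and the shares of nuclei with a UMI of Cd163, Ccr2 and Trem2, were outside this rule and were chosen after the data had been seen. Coordinates are from GENCODE vM21 (build GRCm38, which is mm10).

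The position of MI-DAPA towards the other libraries was read with MI-NS nuclei split at random. Genes at least 2-fold apart were chosen with 1 part of these nuclei, and MI-DAPA was set against the other part. Counting error of MI-NS could thus not produce a return towards Sham-NS. A gene counted as nearer Sham-NS where MI-DAPA lay on the Sham-NS side of that other part. This is a direction only, so a gene that passed beyond Sham-NS was counted too. A deviation of the MI-NS animal, piece of tissue or library is in both parts and was not removed. The same measure within the MI-NS nuclei gave the value without treatment. It covers counting error only and does not show what another untreated heart would give. The log2 ratios and list percentiles, but not this position measure, were tried on counts simulated from the sums of 1 library of each contrast. Changes of 2-fold and 4-fold kept their sign in at least 99.0% of genes, and 95.6% to 96.5% of intervals held the true ratio. The counts were Poisson draws, which the intervals assume, so this checks the computation only. Spread between nuclei and between libraries was not simulated. Alternatives covered nucleus filters, cluster resolution, class by marker level, thinning to 1000 UMIs (which leaves out nuclei with fewer), TMM factors (edgeR 4.0.16), other totals, free RNA, added UMIs and minimum UMIs. Sizes of macrophage-like subclusters had been planned as a comparison and were not compared between libraries, because the genes that define them differ between the libraries. Counts of 2 of them are given only to show which nuclei the list values come from.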

Results

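The data were UMI counts from nuclei of mouse hearts 2 weeks after surgery, in 3 libraries with no replicates: 1 each for Sham-NS, MI-NS and MI-DAPA. Dapagliflozin is an inhibitor of the kidney glucose cotransporter SGLT2, used against diabetes and heart failure. The libraries held 13873275 UMIs in 9744 barcodes for Sham-NS, 10113430 in 7725 for MI-NS and 8871086 in 6354 for MI-DAPA. After filtering, 8296, 7065 and 5372 nuclei were kept, with median depths of 790, 851 and 831 UMIs. Mitochondrial UMIs had a median of 3.32% in Sham-NS, 1.48% in MI-NS and 2.42% in MI-DAPA, so the libraries also differed in a sign of nucleus purity. The nuclear transcript Malat1 made up 5.47%, 9.31% and 5.97% of UMIs. In cardiomyocyte-like nuclei of Sham-NS, MI-NS and MI-DAPA, the Y-linked genes Eif2s3y and Uty stood at 385, 366 and 350 CPM and at 93.1, 83.3 and 78.8 CPM, and Xist, which the inactive X chromosome makes, had 3, 2 and 4 UMIs.

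Cell composition was compared first, since infarction replaces muscle with scar and brings in immune cells. Cardiomyocyte-like nuclei made up 19.2% (18.3 to 20.0) of Sham-NS, 13.4% (12.6 to 14.2) of MI-NS and 26.5% (25.3 to 27.7) of MI-DAPA nuclei. Fibroblast-like nuclei, the makers of scar matrix, were at 21.01% (20.1 to 21.9), 29.1% (28.0 to 30.2) and 24.9% (23.8 to 26.1). Macrophage-like nuclei were at 9.06% (8.46 to 9.70), 12.0% (11.2 to 12.8) and 6.89% (6.22 to 7.60), so their share in MI-DAPA was 0.576 (0.508 to 0.651) of that in MI-NS, a log2 ratio of -0.80. This ratio was -1.60 under the stricter nucleus filter, -1.38 in nuclei thinned to 1000 UMIs and -0.60 with class by marker level. Vascular endothelial-like nuclei were at 20.7% (19.9 to 21.6), 13.3% (12.5 to 14.1) and 18.1% (17.1 to 19.1). Within the fibroblast-like nuclei, a cluster led by Dpep1 and Abca8a held 1591 Sham-NS, 26 MI-NS and 152 MI-DAPA nuclei. Another, led by Comp, Ltbp2, Thbs1 and Postn, held 11, 1283 and 446, and a cluster led by Vcan, Col5a3 and Pi16 held 141, 746 and 741. A small cardiomyocyte-like cluster led by Myh7, Nppa and Ankrd1 held 3, 155 and 47 nuclei. The fibroblast-like ratios turned direction at Leiden resolution 2.0, where a cluster led by Comp stayed unnamed. For MI-NS against Sham-NS the fibroblast-like log2 ratio was 0.47, but 1.53 in thinned nuclei and 0.94 with class by marker level. For MI-DAPA against MI-NS it was -0.22, but -1.08 and -0.55. The cardiomyocyte-like ratio of MI-NS against Sham-NS was -0.52, and -1.06 under the stricter nucleus filter, where a cluster led by Myh7 and Nppa stayed unnamed. The higher macrophage-like share of MI-NS over Sham-NS was lost when class was read from marker levels, with a log2 ratio of -0.04, or when only nuclei with at least 1000 UMIs were used and thinned to that number, with -0.16. The latter leaves out most macrophage-like nuclei, so depth and choice of nuclei change together there. The lower vascular endothelial-like share of MI-NS than of Sham-NS shrank to a log2 ratio of -0.25 under the stricter nucleus filter and to -0.01 in thinned nuclei. In thinned nuclei the share of MI-DAPA in this class lay below that of MI-NS, with a log2 ratio of -0.74.

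**Figure D1:**
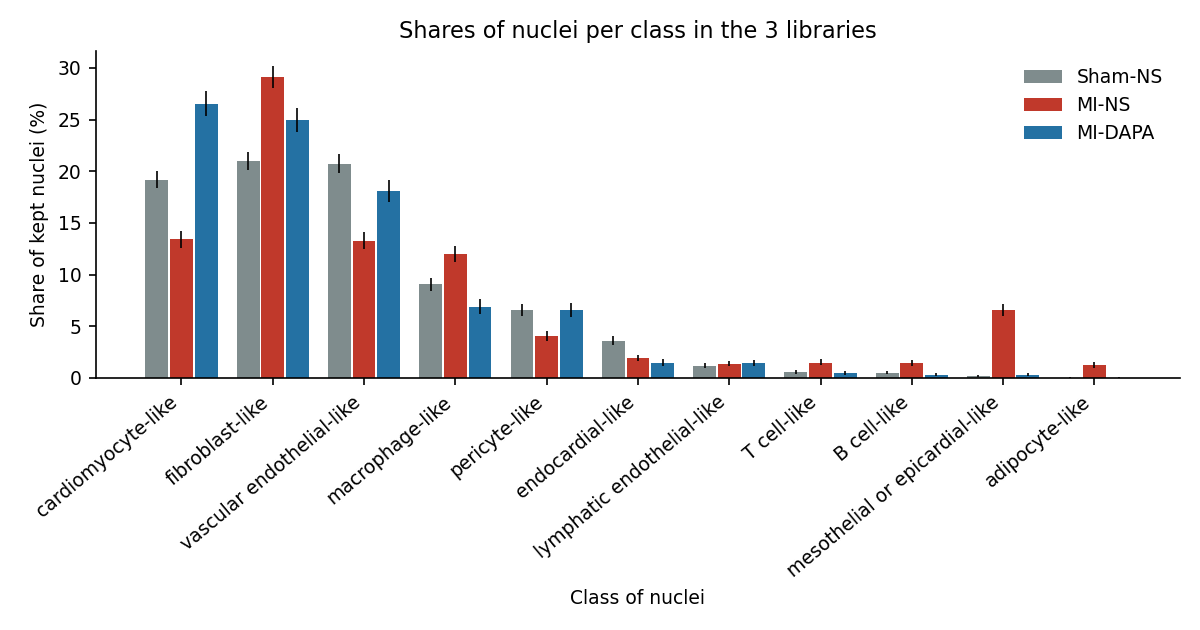
Share of kept nuclei in percent (vertical axis) for 11 classes of nuclei, with 1 bar per library and 95% Clopper-Pearson intervals that cover counting error only. Cardiomyocyte-like nuclei stood at 19.2%, 13.4% and 26.5% in Sham-NS, MI-NS and MI-DAPA, and macrophage-like nuclei at 9.06%, 12.0% and 6.89%.

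The contrast of MI-NS with Sham-NS asks what the infarcted heart looks like without the drug. The labels give no hour of collection, and clock genes differed between these libraries in every class looked at, so that hour and infarction are not separated for any gene in this contrast. In cardiomyocyte-like nuclei, stress and fetal genes were higher in MI-NS: 19 of 22 measurable members were higher, 11 of them at least 2-fold, and the median log2 ratio was 1.19 (1.02 to 1.25), above all 10000 random lists. The natriuretic peptide gene Nppa stood at 403 against 22.9 CPM, a log2 ratio of 4.13 (3.82 to 4.47), and Nppb had a ratio of 4.24 (3.92 to 4.59). Nppa was also at 185, 107 and 136 CPM in vascular endothelial-, fibroblast- and macrophage-like nuclei of MI-NS, against 8.64, 3.79 and 1.92 in Sham-NS, so its RNA was also higher in MI-NS outside cardiomyocyte-like nuclei. Nppa (ENSMUSG00000041616) lies on chromosome 4 at 148000722 to 148002079 in mm10. Myh7, the slow myosin heavy chain of the fetal mouse ventricle, was higher by 4.02 (3.81 to 4.23), and Ankrd1, a stretch-responsive sarcomere protein, by 3.99 (3.85 to 4.13). Myh6, the adult fast myosin, was lower by -0.79 (-0.80 to -0.77). Sprr1a, a stress-induced small proline-rich protein, had 51 UMIs in MI-NS and 0 in Sham-NS, at least 32.3-fold higher, and Nmrk2, a nicotinamide riboside kinase, was higher by 4.41 (3.24 to 6.21). Among genes eligible for naming, the lowest ratios were those of the carboxylesterase Ces1d (-5.25, -5.87 to -4.74), the clock-controlled repressor Ciart (-3.94, -5.52 to -2.91) and the zinc finger gene Zfp970 (-3.33, -4.23 to -2.63).

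Among the ion and fuel lists of cardiomyocyte-like nuclei, potassium channels were lower, with 8 of 13 members lower, a median of -0.55 (-0.69 to -0.28) and percentile 0.010. Kcnv2, a modifier of voltage-gated channels, had a ratio of -2.99 (-3.73 to -2.38), and Kcnip2, a subunit of the fast transient outward current, -1.03 (-1.21 to -0.86). Fatty acid oxidation had a median of 0.27 (0.19 to 0.38) with 24 of 30 members higher, led by Pdk4, a brake on glucose oxidation, at 3.63 (3.20 to 4.10), and by the fatty acid carrier Fabp3 at 1.31 (1.16 to 1.46). Glycolysis and glucose uptake stood at -0.29 (-0.32 to -0.10), oxidative phosphorylation at -0.14 (-0.25 to -0.08) and ketone metabolism at -0.20 (-0.36 to -0.07), where the ketone-using enzyme Oxct1 was at -1.07 (-1.29 to -0.87). Calcium handling was at -0.14 (-0.21 to -0.03), sodium and hydrogen transport at 0.07 (-0.03 to 0.28) and adult sarcomere genes at 0.14 (0.09 to 0.20). With TMM factors, fatty acid oxidation was at 0.12, glycolysis at -0.43, oxidative phosphorylation and calcium handling at -0.28, potassium channels at -0.70 and sodium and hydrogen transport at -0.08. The sarcomere median was then 0.00 to 2 decimals and on the other side of 0. TMM shifted the median of all measurable cardiomyocyte genes: CPM ratios lay 0.14 above TMM ratios here, with 0.13 in fibroblast-like and 0.12 in vascular endothelial-like nuclei, and -0.18 in cardiomyocyte-like nuclei for MI-DAPA against MI-NS.

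Fibroblast-like nuclei of MI-NS carried a scar-forming profile. Of 24 measurable genes of activated fibroblasts and myofibroblasts, 23 were higher and 22 at least 2-fold so, with a median log2 ratio of 2.95 (2.68 to 3.17), above all 10000 random lists. Fibrillar collagen and matrix genes were higher in 26 of 27, 18 of them at least 2-fold, with a median of 2.10 (1.85 to 2.19), also above all of them. Postn, the matrix protein periostin, stood at 1756 against 61.5 CPM, a ratio of 4.83 (4.52 to 5.17). Postn (ENSMUSG00000027750) lies on chromosome 3 at 54361109 to 54391037. The main fibrillar collagen gene Col1a1 stood at 1779 against 199.5 CPM (3.15, 2.97 to 3.34), and fibronectin, Fn1, at 1092 against 46.3 CPM (4.55, 4.19 to 4.95). Cthrc1, a secreted protein of activated fibroblasts, had 179 UMIs in MI-NS and 0 in Sham-NS, at least 43.4-fold higher. The secreted Wnt-induced protein Ccn4 was at 95 against 0 UMIs, at least 23.1-fold higher, and Kif26b had 256 against 1 UMIs, a ratio of 6.96 (5.05 to 12.85). Matrifibrocyte genes had a median of 1.66 (1.38 to 2.26) with all 6 members higher, among them the cartilage matrix gene Comp at 5.73 (5.19 to 6.41). The TGF-beta pathway stood at 0.50 (0.25 to 0.74), with the matricellular gene Ccn2 at 2.99 (2.73 to 3.26).

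Genes of quiescent fibroblasts were lower in 15 of 19, with a median of -0.61 (-0.71 to -0.46), below all random lists. The dipeptidase Dpep1 was at -2.74 (-3.04 to -2.47), the ferritin receptor Scara5 at -2.40 (-2.98 to -1.89) and Hsd11b1, which activates glucocorticoids, at -3.35 (-4.46 to -2.50). The lowest ratios of eligible genes belonged to periplakin, Ppl (-7.24, -9.00 to -6.15), the methyltransferase Inmt (-5.00, -7.52 to -3.61) and the clock gene Per2 (-4.78, -5.41 to -4.26). Without the Vcan-led cluster, the activated list had a median of 3.54 and the matrix list 2.34. Collagen RNA was also higher outside its source in MI-NS: Col1a1 stood at 274 against 7.67 CPM in macrophage-like and at 301 against 17.3 CPM in vascular endothelial-like nuclei, which should lack it. Free RNA and doublets with fibroblasts would both give this, and they were not separated.

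Vascular endothelial-like nuclei of MI-NS had more transcript of vessel growth genes. Of 17 angiogenesis genes 14 were higher, with a median of 0.62 (0.46 to 0.93), above all random lists, but 0.36 with class by marker level and 0.30 in thinned nuclei. The basement membrane collagens Col4a1 and Col4a2 were at 1.83 (1.61 to 2.04) and 1.85 (1.62 to 2.09), the laminin Lamb1 at 1.42 (1.02 to 1.83) and the netrin receptor Unc5b at 1.41 (0.88 to 1.96). Endothelial activation genes had a median of 0.19 (-0.01 to 0.34), with endothelin, Edn1, at 1.59 (0.93 to 2.30). Capillary genes were at -0.02 (-0.24 to 0.12): the carbonic anhydrase Car4 was at -1.41 (-1.87 to -0.99) and lipoprotein lipase, Lpl, at -1.09 (-1.38 to -0.81), while Cdh13 was at 1.30 (0.89 to 1.71). Arterial and venous genes were at -0.06 (-0.16 to 0.26), with the elastic fibre gene Fbln5 at 2.44 (1.52 to 3.55). The extremes of eligible genes were Per2 (-5.25, -6.46 to -4.39), the kinase Map3k6 (-3.71, -5.14 to -2.73) and the protease inhibitor Timp4 (-3.11, -4.02 to -2.41) at the low end. At the high end were the clock activator Arntl (4.79, 3.38 to 7.32), Cpne7 (4.35, 3.18 to 6.15) and the immediate early receptor Nr4a1 (3.54, 2.81 to 4.43).

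Macrophage-like nuclei are named by the series as the cells of interest. In MI-NS they had less of the resident programme, with 11 of 15 members lower, a median of -0.45 (-0.52 to -0.30) and percentile 0.430. This median was -0.16 with class by marker level and -0.14 in thinned nuclei. Cd163, a haemoglobin scavenger receptor of resident cells, stood at 317 against 1199 CPM, a ratio of -1.92 (-2.16 to -1.69). Cd163 (ENSMUSG00000008845) lies on chromosome 6 at 124304656 to 124330527. The hyaluronan receptor Lyve1 was at -1.14 (-1.81 to -0.52), while the growth factor Igf1 (1.30, 0.86 to 1.77) and complement C4b (1.43, 1.15 to 1.72) were higher. The lipid-associated Trem2 programme was higher in 12 of 14 members, with a median of 1.04 (0.62 to 1.24), above all random lists, but 0.32 over members with at least 200 UMIs. Among its members the galectin Lgals3 was at 1.94 (1.21 to 2.83), the lipid droplet protein Plin2 at 1.65 (0.85 to 2.61) and the protease Ctsd at 1.46 (1.06 to 1.89). Class II antigen presentation was higher in 7 of 8 members, with a median of 0.79 (0.57 to 0.97), H2-Aa at 1.10 (0.73 to 1.48) and H2-Eb1 at 1.09 (0.73 to 1.47). The recruitment receptor Ccr2 stood at 367 (321 to 418) CPM in MI-NS and 132 (103 to 167) in Sham-NS, and Trem2 at 244 (206 to 286) and 94.0 (69.5 to 124).

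Inflammatory cytokines and chemokines of these nuclei had a median of 0.37 (0.02 to 0.67), with 6 of 9 members higher. Il1b, the inflammasome-dependent cytokine, was at 1.89 (0.98 to 3.04) and the chemokine Ccl8 at 3.46 (2.18 to 5.54), whereas Ccl7 was at -1.16 (-1.95 to -0.44). Inflammasome and NF-kB genes had a median of 0.28 (0.09 to 0.44), complement and phagocytosis 0.26 (0.15 to 0.43), interferon response -0.21 (-0.33 to -0.01) and alternative activation -0.25 (-0.48 to 0.01). The inhibitory receptor Cd300lf had 60 against 0 UMIs, at least 16.9-fold higher, the terminal complement gene C6 was at 5.12 (3.16 to 11.02), and Arntl at 4.18 (2.56 to 7.57). Lowest of the eligible genes beside Cd163 were the clock gene Per1 (-2.70, -3.60 to -1.95) and Fkbp5, a glucocorticoid target (-2.28, -3.32 to -1.43). Mmp12, a macrophage elastase, was at 2.69 (1.57 to 4.30) but at -0.23 in thinned nuclei. In thinned nuclei the interferon median was also on the other side of 0, at 0.07.

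**Figure D2:**
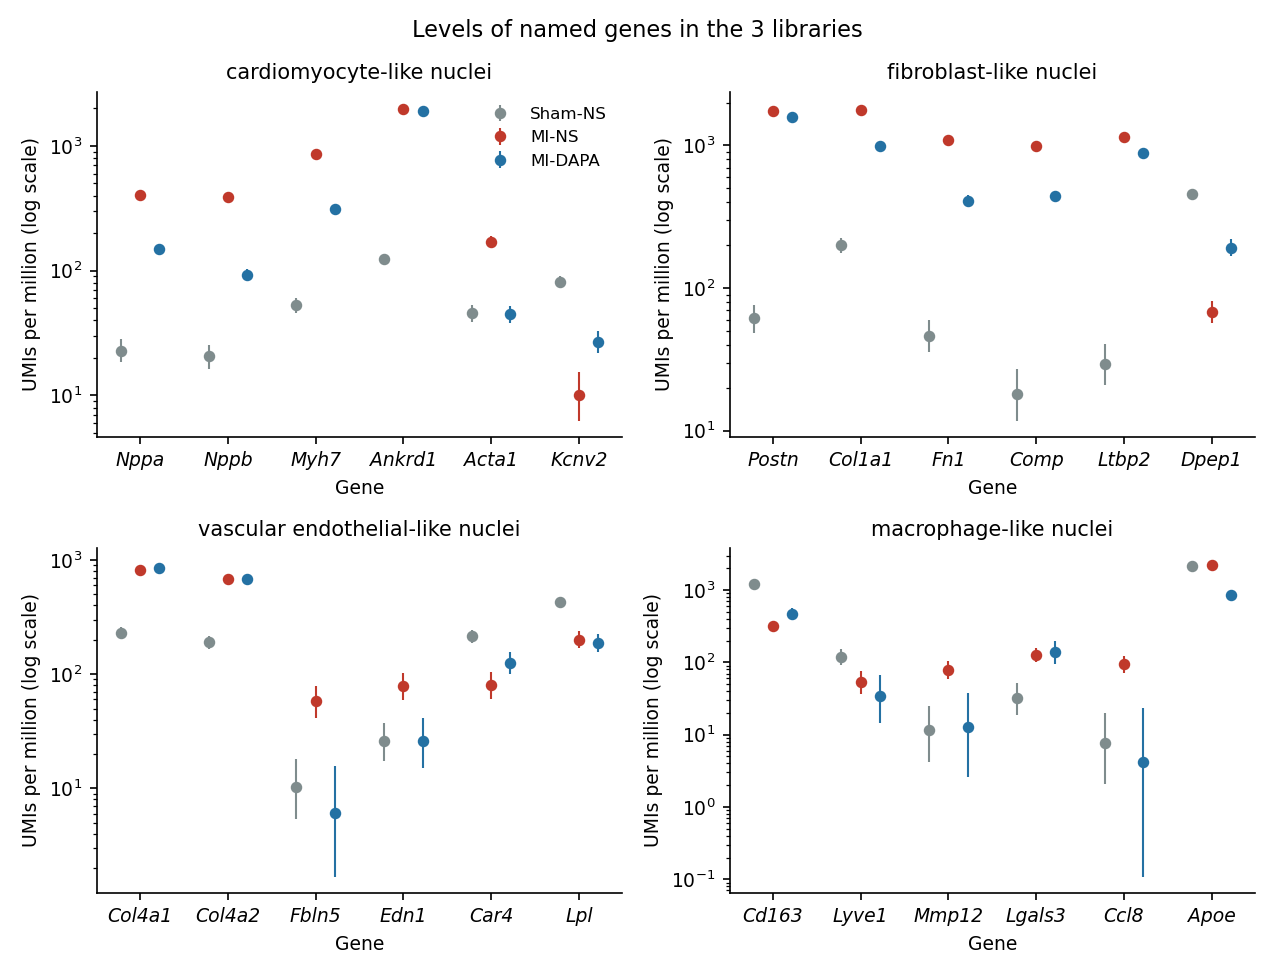
CPM (vertical axis, log scale) of 6 named genes in each of 4 classes, with 1 point per library and 95% Poisson intervals. Nppa in cardiomyocyte-like nuclei stood at 22.9, 403 and 148 in Sham-NS, MI-NS and MI-DAPA, and Postn in fibroblast-like nuclei at 61.5, 1756 and 1585.

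Lists read in every class moved alike in several classes. Immediate early and heat shock genes were higher in MI-NS than in Sham-NS in cardiomyocyte-like (0.51, 0.35 to 0.72), vascular endothelial-like (0.76, 0.42 to 0.91) and macrophage-like nuclei (0.64, 0.33 to 0.97), with 0.29 (-0.01 to 0.58) in fibroblast-like nuclei. Over members with at least 200 UMIs the vascular endothelial-like median was -0.003, so its direction was lost. Unfolded protein and oxidative stress genes had medians of 0.26 (-0.13 to 0.38), 0.24 (-0.02 to 0.40), 0.32 (0.06 to 0.59) and 0.23 (-0.07 to 0.58) in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei. Mitochondrially encoded genes were lower in all 4 classes, at -0.72 (-0.76 to -0.64), -1.11 (-1.17 to -1.06), -1.02 (-1.04 to -0.88) and -1.12 (-1.18 to -1.06). Haemoglobin genes, a sign of blood RNA, were at -0.18 (-0.57 to 0.19), -0.92 (-1.32 to -0.59), -0.48 (-1.005 to 0.11) and -1.005 (-1.58 to -0.53). Of 26 cell cycle genes at most 3 were measurable in any class, with medians between -0.66 and -0.18.

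The contrast of MI-DAPA with MI-NS asks how infarcted hearts differ with and without dapagliflozin. The labels give no hour of collection here either, so hour and treatment are not separated. In cardiomyocyte-like nuclei, stress and fetal genes were lower in MI-DAPA in 17 of 22 members, 7 of them at least 2-fold, with a median of -0.41 (-0.48 to -0.29), below all random lists. It was -0.23 with TMM factors and -0.20 under the stricter nucleus filter, where a cluster of 222 nuclei led by Myh7, Nppa and Nppb stayed unnamed. In the main setting, the cluster led by Myh7, Nppa and Ankrd1 held 155 of 947 cardiomyocyte-like nuclei in MI-NS and 47 of 1425 in MI-DAPA. A different share of this cluster was not separated from a change within nuclei. Nppb was at -2.08 (-2.27 to -1.90), skeletal actin, Acta1, at -1.92 (-2.20 to -1.65), Myh7 at -1.46 (-1.57 to -1.35), Nppa at -1.44 (-1.60 to -1.29) and the calcineurin target Rcan1 at -1.45 (-1.82 to -1.09). Myh6 was higher by 0.51 (0.49 to 0.52). Sprr1a had 3 UMIs against 51 (-4.68, -7.21 to -3.26), and Nmrk2 was at -2.62 (-3.51 to -1.85). The stress hormone gene Gdf15 was at -2.32 (-3.34 to -1.45), but at 0.89 under the stricter nucleus filter, where the naming of clusters changed as well. Highest of the eligible genes in MI-DAPA were the angiotensin-(1-7) receptor gene Mas1 (1.80, 0.78 to 3.16), Zfp970 (1.59, 0.82 to 2.53) and Rp1 (1.52, 0.62 to 2.65). Potassium channels were higher in 10 of 13 members, with a median of 0.15 (0.04 to 0.31), Kcnv2 at 1.39 (0.73 to 2.17) and the transient outward channel Kcnd2 at 1.05 (0.46 to 1.71).

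Fatty acid oxidation genes were lower in 23 of 30 members of these nuclei, with a median of -0.23 (-0.31 to -0.15), Pdk4 at -1.11 (-1.35 to -0.87) and Fabp3 at -0.89 (-1.03 to -0.74), while the lipid-sensing factor Ppara was at 0.82 (0.45 to 1.22). Calcium handling had a median of 0.23 (0.05 to 0.25), with the calcium release channel Ryr2 at 0.56 (0.52 to 0.59). Ketone metabolism was at -0.12 (-0.32 to 0.03), oxidative phosphorylation at -0.05 (-0.15 to 0.03), sodium and hydrogen transport at -0.08 (-0.12 to 0.12) and adult sarcomere genes at -0.05 (-0.08 to 0.03). Glycolysis and glucose uptake was at -0.14 (-0.24 to -0.02). With TMM factors, fatty acid oxidation was at -0.06, calcium handling at 0.41, oxidative phosphorylation and adult sarcomere genes at 0.13, ketone metabolism at 0.06 and glycolysis at 0.04, so the size of these list values, and for several their direction, depends on the scaling.

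Fibroblast-like nuclei of MI-DAPA kept the scar matrix profile, with lower list medians. The cluster led by Comp and Postn held 1283 of 2055 nuclei of this class in MI-NS and 446 of 1339 in MI-DAPA. The Vcan-led cluster held 746 and 741. This different mix of clusters was not separated from a change within nuclei. Activated fibroblast and myofibroblast genes were lower than in MI-NS in 18 of 24, with a median of -0.59 (-0.67 to -0.41), and matrix genes in 20 of 28, with -0.38 (-0.49 to -0.32), both below all random lists. The contractile genes Acta2 (-2.44, -3.90 to -1.41) and Tagln (-1.94, -2.52 to -1.43) were among the lowest of the lists. Fn1 was at -1.42 (-1.57 to -1.27), thrombospondin, Thbs1, at -1.30 (-1.52 to -1.09) and Col1a1 at -0.83 (-0.93 to -0.73), whereas Postn was at -0.15 (-0.23 to -0.06). Matrifibrocyte genes had a median of -0.79 (-1.12 to -0.50), with Comp at -1.16 (-1.31 to -1.02). Quiescent genes were at -0.06 (-0.21 to 0.04), with Dpep1 at 1.48 (1.16 to 1.82) and the laminin Lama2 at 0.96 (0.82 to 1.10), and the TGF-beta pathway was at 0.09 (-0.07 to 0.22). Lowest of the eligible genes were the hyaluronan-degrading protein Cemip (-3.24, -4.14 to -2.53), the activin binder follistatin, Fst (-3.04, -4.36 to -2.09), and the imprinted RNA H19 (-2.76, -4.85 to -1.47). Highest were Ppl (4.04, 2.85 to 5.84), the glucocorticoid-responsive factor Zbtb16 (2.25, 1.71 to 2.84) and the collagen Col6a6 (1.85, 1.35 to 2.37). Without the Vcan-led cluster the activated median was -0.36 and the matrix median -0.17, and in thinned nuclei the activated median was -0.19.

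In vascular endothelial-like nuclei, arterial and venous genes were lower in MI-DAPA in all 7 measurable members, with a median of -0.59 (-0.81 to -0.28) at percentile 0.060. The venous factor Nr2f2 was at -0.75 (-1.31 to -0.22) and the arterial factor Sox17 at -0.69 (-1.08 to -0.31). The arterial cluster, led by Sema3g and Sox17, held 75 of 938 nuclei of this class in MI-NS and 58 of 971 in MI-DAPA, and a change in their number was not separated from a change within nuclei. Angiogenesis genes stood at 0.03 (-0.10 to 0.10), capillary genes at -0.01 (-0.26 to 0.15) and endothelial activation at -0.23 (-0.40 to 0.01), with Edn1 at -1.57 (-2.48 to -0.79). Lowest of the eligible genes were the injury matrix gene Tnc (-2.002, -3.15 to -1.08), Vapa (-1.94, -3.15 to -0.97) and B2m, the light chain of class I antigen presentation (-1.81, -2.20 to -1.45). Highest were Erich1 (1.86, 0.92 to 3.02), Akap8 (1.57, 1.26 to 1.90) and the Wnt regulator Axin1 (1.34, 0.50 to 2.30), of which Erich1 was at -0.14 in thinned nuclei.

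Macrophage-like nuclei of MI-DAPA, 370 in number, had less transcript of several activation lists than those of MI-NS. Class II antigen presentation was lower in 7 of 8 members, with a median of -0.70 (-0.88 to -0.45), below all random lists, and H2-Eb1 at -0.96 (-1.48 to -0.49). The interferon response was lower in 11 of 13, with a median of -0.54 (-0.81 to -0.36) at percentile 0.040 and Oasl2 at -0.91 (-1.47 to -0.42). The lipid-associated Trem2 programme was lower in 11 of 15, with a median of -0.58 (-1.004 to -0.22) that was -0.15 with class by marker level and -0.17 in thinned nuclei, the lipid carrier Apoe at -1.38 (-1.60 to -1.17) and Ctsd at -1.24 (-1.82 to -0.73), but Trem2 itself at 233 (176 to 304) CPM against 244. Complement and phagocytosis was at -0.30 (-0.46 to -0.04), with C1qa at -1.16 (-1.53 to -0.82). Lowest of the eligible genes were Ccl8 with 1 UMI against 58 (-3.90, -9.80 to -1.94), C6 with 3 against 61 (-2.75, -5.28 to -1.34) and Mmp12 with 3 against 49 (-2.44, -4.97 to -1.01), of which Mmp12 was at 0.13 with class by marker level. Highest were Slu7 (1.76, 0.94 to 2.62), Fer (1.48, 0.71 to 2.25) and Mill2 (1.47, 0.73 to 2.22), with Mill2 at -0.64 in thinned nuclei.

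The inflammatory genes themselves were sparse. The 5 measurable cytokines and chemokines had a median of -0.63 (-1.29 to 0.05), the same value as that of Il1b, at -0.63 (-1.72 to 0.26), so a difference in Il1b was not detectable at this depth. Tnf had 6 UMIs against 26, a ratio of -0.64 (-2.30 to 0.58), and Spp1 3 against 7 (0.29, -2.42 to 2.29). The scavenger chemokine Cxcl16 was higher, at 1.03 (0.77 to 1.28). Inflammasome and NF-kB genes stood at -0.01 (-0.23 to 0.20), with the RNA sensor Tlr7 at 1.32 (0.70 to 1.94). Resident macrophage genes had a median of 0.32 (0.03 to 0.38), with the mannose receptor Mrc1 at 0.78 (0.60 to 0.96) and Cd163 at 0.55 (0.19 to 0.89), and alternative activation had 0.38 (0.01 to 0.48). Both of these medians were on the other side of 0 with no minimum of UMIs, at -0.10 and -0.33, and the resident median also in thinned nuclei, at -0.05. Ccr2 stood at 208 (154 to 275) CPM in MI-DAPA.

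Read across classes, immediate early and heat shock genes were lower in MI-DAPA than in MI-NS in cardiomyocyte-like (-0.80, -1.03 to -0.57), vascular endothelial-like (-0.45, -0.67 to -0.20) and macrophage-like nuclei (-0.51, -0.81 to -0.12), with -0.09 (-0.29 to 0.08) in fibroblast-like nuclei. Unfolded protein and oxidative stress genes were at -0.45 (-0.59 to -0.15), -0.33 (-0.43 to -0.08), -0.15 (-0.49 to 0.07) and -0.19 (-0.53 to 0.19) in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei. Mitochondrially encoded genes were higher in all 4 classes, at 0.38 (0.35 to 0.47), 0.86 (0.81 to 0.91), 0.66 (0.61 to 0.73) and 0.90 (0.80 to 0.97). Haemoglobin genes were at -1.14 (-1.65 to -0.69), -0.32 (-0.80 to 0.07) and -0.99 (-1.62 to -0.43) in the first 3 of these classes and had no measurable member in macrophage-like nuclei. Cell cycle genes, with 1 to 3 measurable per class, had medians between 0.12 and 0.95. Long genes were relatively higher in MI-DAPA than in MI-NS, with a Spearman correlation across genes, which are not independent replicates, of 0.20 to 0.25 between ratio and gene length in the 4 classes.

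**Figure D3:**
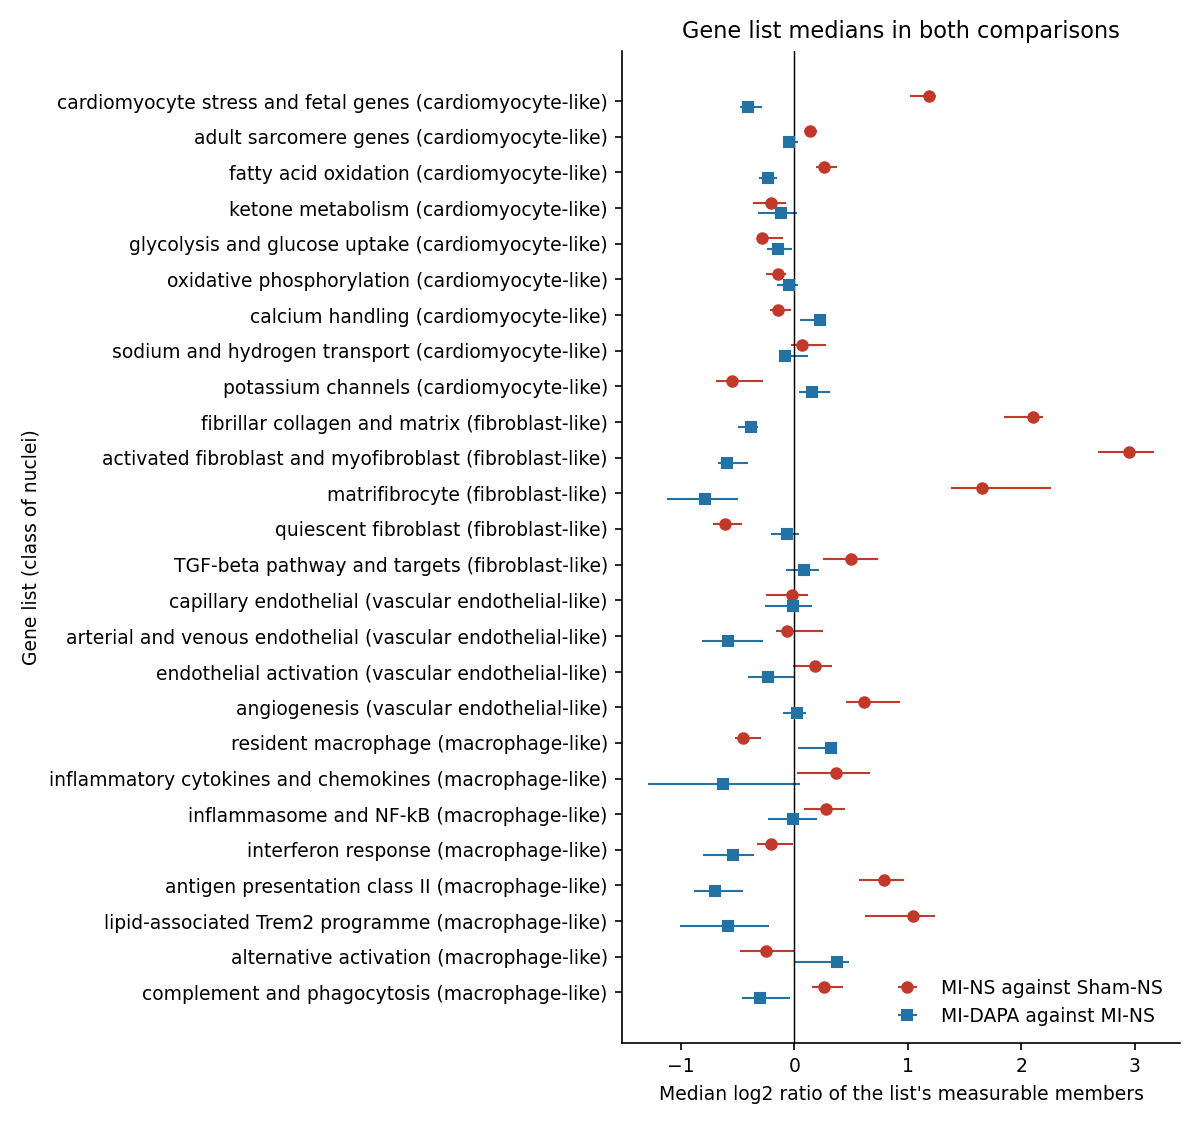
Median log2 ratio of each gene list's measurable members (horizontal axis), with 95% intervals from counting error, for MI-NS against Sham-NS (circles) and MI-DAPA against MI-NS (squares). Activated fibroblast genes stood at 2.95 and -0.59, cardiomyocyte stress genes at 1.19 and -0.41, and the Trem2 programme at 1.04 and -0.58.

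The contrast of MI-DAPA with Sham-NS shows what remained different from the uninjured heart. Cardiomyocyte stress genes had a median of 0.68 (0.57 to 0.75), activated fibroblast genes 1.94 (1.70 to 2.20), matrix genes 1.64 (1.53 to 1.74), quiescent fibroblast genes -0.62 (-0.86 to -0.49) and angiogenesis genes 0.62 (0.35 to 0.80). In macrophage-like nuclei the Trem2 programme stood at -0.05 (-0.36 to 0.29), class II antigen presentation at 0.07 (-0.16 to 0.33) and the interferon response at -0.75 (-0.92 to -0.49). Ankrd1 was at 3.95 (3.82 to 4.08), Nppa at 2.69 (2.37 to 3.03), Postn at 4.68 (4.37 to 5.03) and Cd163 at -1.37 (-1.68 to -1.08).

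Genes at least 2-fold apart between MI-NS and Sham-NS were taken, and those where MI-DAPA lay on the Sham-NS side of MI-NS were counted as nearer Sham-NS. This gives the direction of a difference, not its distance from Sham-NS. It held for 83.0% of 675 genes in cardiomyocyte-like, 85.6% of 855 in fibroblast-like, 76.1% of 473 in vascular endothelial-like and 81.3% of 246 in macrophage-like nuclei. The values without treatment, from the MI-NS library set against itself, were 50.8%, 49.0%, 48.8% and 50.8%. The share was larger for genes higher in MI-NS (89.9%, 87.4%, 81.1% and 83.7%) than for genes lower in MI-NS (68.8%, 82.3%, 68.4% and 78.1%). With the median ratio of all measured genes of the class subtracted, these were 83.5%, 85.9%, 81.1% and 86.5%, and 75.6%, 83.0%, 68.4% and 78.1%. For genes at least 1.5-fold apart the order turned in fibroblast-like (79.6% and 80.2%) and macrophage-like nuclei (74.0% and 74.6%), but not in the other classes. The median return was 44.3%, 36.0%, 39.4% and 47.9% of the difference, and over 20 other splits of the MI-NS nuclei the share of genes stayed between 75.5% and 87.2%. Over those splits the values without treatment lay between 42.0% and 59.7%, both in macrophage-like nuclei. The splits were not run for the subtraction of other classes. Much of the return was shared between classes: with the median ratio of the other 3 classes subtracted gene by gene, the shares were 69.6%, 64.0%, 55.9% and 54.3%, against 51.2%, 52.6%, 47.7% and 53.8% without treatment. These cover the 461, 589, 415 and 210 genes measured in another class, for which the shares as counted were 86.8%, 87.3%, 76.6% and 80.5%. With this subtraction the order of genes higher and lower in MI-NS also turned in fibroblast-like (56.6% and 77.5%) and macrophage-like nuclei (50.9% and 58.3%). Genes are not independent replicates, and each library is 1 sample. The median mitochondrial share and the share of Malat1 of MI-DAPA also lay between those of the other libraries.

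Transcripts of the drug's target were nearly absent. Slc5a2, which encodes SGLT2, had 13, 11 and 14 UMIs in all kept nuclei of Sham-NS, MI-NS and MI-DAPA, in 4, 2 and 2 nuclei. Slc5a2 (ENSMUSG00000030781) lies on chromosome 7 at 128265657 to 128272430. It had no UMI in any cardiomyocyte-like or macrophage-like nucleus: 0 of 752, 846 and 370 macrophage-like nuclei, which allows shares of nuclei with a UMI of up to 0.399%, 0.355% and 0.811%. Of the 38 UMIs, 35 were in 5 nuclei that also held 9 to 33 UMIs of Slc34a1 and 3 to 7 of Lrp2, genes of the kidney tubule. These 5 lay in lymphatic endothelial-like (3), fibroblast-like (1) and pericyte-like clusters (1), so their cluster names describe them poorly. The other 3 nuclei had 1 UMI of Slc5a2 each and none of Slc34a1 or Lrp2. Slc5a1, which encodes the related transporter SGLT1, had 2 UMIs in kept nuclei of Sham-NS and 0 in those of the other libraries. Nlrp3, the inflammasome sensor, was found mostly in macrophage-like nuclei, at 36.4 (21.9 to 56.9), 58.5 (40.9 to 80.9) and 55.2 (29.4 to 94.3) CPM from 19, 36 and 13 UMIs, and no difference was detectable at this depth.

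Subsets of macrophage-like nuclei were read from 6 subclusters, which were led by Cd163 and F13a1, by Ccr2 with class II genes, by Clec10a, Ccl6 and Folr2, by Lgals3 and Trem2, by the interferon genes Ifit3 and Irf7, and by the proliferation gene Mki67. The first held 377 Sham-NS, 49 MI-NS and 97 MI-DAPA nuclei, and the subcluster led by Lgals3 and Trem2 held 29, 249 and 90, so the resident and Trem2 list values come from different mixes of nuclei. With nuclei thinned to 500 UMIs, Cd163 was seen in 35.5% (32.1 to 39.0) of macrophage-like nuclei of Sham-NS, 10.4% (8.43 to 12.7) of MI-NS and 16.5% (12.9 to 20.7) of MI-DAPA, beside 1.58%, 0.691% and 0.640% of all other nuclei. Ccr2 was seen in 4.26% (2.93 to 5.95), 11.8% (9.72 to 14.2) and 6.76% (4.42 to 9.81), beside 0.358%, 0.884% and 0.340%. Trem2 was seen in 4.12% (2.82 to 5.80), 10.8% (8.75 to 13.04) and 10.5% (7.60 to 14.1), beside 0.133%, 0.611% and 0.280%. The median depth of macrophage-like nuclei before thinning was 630.5, 654.5 and 591.5 UMIs.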

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

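The tests in this part were chosen after the result was seen. Mesothelial-like and adipocyte-like nuclei, whose shares were not among the planned comparisons but which count in the total of every share, were almost confined to 1 library. Mesothelial-like nuclei, led by Muc16, Msln and Wt1, made up 6.54% (5.97 to 7.14) of MI-NS nuclei against 0.181% (0.101 to 0.298) of Sham-NS, 35.0 (21.7 to 65.1) times the share. Over all libraries this cluster held 492 nuclei, but 236 at Leiden resolution 0.5, where its shares were not compared, so its size depends on the resolution. Its MI-NS nuclei had UMIs of a median of 1 of the 8 markers, against 3 in the 15 Sham-NS nuclei. Adipocyte-like nuclei, led by Car3, Adrb3 and Plin1, made up 1.23% of MI-NS against 0.0241% of Sham-NS, from 87 against 2 nuclei.

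Free RNA as the source of this pattern was not tested independently, because the clusters were named by the same markers. In MI-NS, 80.2% of the mesothelial marker UMIs lay in the mesothelial-like nuclei, which held 8.45% of all UMIs, a ratio of 9.50, but naming alone sets it above 1. Of the adipocyte marker UMIs, 47.7% lay in the adipocyte-like nuclei, a ratio of 23.6. All kept nuclei held 2833 of these UMIs in MI-NS and 3562 in Sham-NS. A piece of tissue with more outer surface and fat could give both classes at once, and the adipocyte-like 1.23% goes with it. The total of adipocyte marker UMIs cannot decide, since in Sham-NS only 20 of the 3562 lay in adipocyte-like nuclei. Infarction itself may also raise mesothelial-like nuclei, but the other infarcted library, MI-DAPA, held 0.279% (0.156 to 0.460). Free RNA stays open for want of an independent test. With 1 library per group, infarction, treatment and the piece of tissue cannot be told apart. A count of nuclei by place in the heart, which would separate them, was not possible here.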

How the results depend on the processing

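Keeping mixed clusters, removing nuclei with doublet scores over 0.15, removing the length trend, subtracting the library-wide profile for the position of MI-DAPA, leaving out the Vcan-led cluster, subtracting the other classes or all measured genes and guarding list members against free RNA were tests chosen after the data had been seen. Values are log2 ratios, and the cause of each move was not tested unless given. In each list the first contrast is MI-NS against Sham-NS and the second MI-DAPA against MI-NS. Keeping doublets moved nothing because no doublet was called, so it says nothing about stability and is not counted here. Of 64 values of shares of nuclei under other settings, 37 stayed within their counting interval, 22 moved with the same sign and 5 reversed, and of 27 values of the position of MI-DAPA, 17 stayed and 10 moved. For lists and named genes, a reversal was counted only where the main interval excluded 0. Values counted as stayed or moved can therefore differ in sign from the main value, as several list medians did with TMM factors. Of 900 values of lists other than stress, matrix, activated fibroblast, resident macrophage, Trem2 programme and angiogenesis, 797 stayed, 98 moved and 5 reversed. Of 3727 values of named genes, 3421 stayed, 297 moved and 9 reversed. Adding 2 UMIs and removing nuclei by doublet score moved none of them, and subtracting free RNA moved none of the 240 values it was run on and so says little about free RNA. No paired analysis was possible because each group is 1 library. Depth limits sparse genes: Il1b, Tnf and Nlrp3 had few UMIs in macrophage-like nuclei, and thinning to 1000 UMIs kept only 3018, 2830 and 2152 nuclei.

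Under the stricter filter on nuclei, first-contrast shares were -1.06 for cardiomyocyte-like, 0.68 for fibroblast-like, -0.25 for vascular endothelial-like and 0.72 for macrophage-like nuclei. Second-contrast shares were 1.28 for cardiomyocyte-like, 0.19 for vascular endothelial-like and -1.60 for macrophage-like nuclei. Cardiomyocyte stress genes were at 0.77 and -0.20, matrix genes at 1.83 in the first contrast and activated fibroblast genes at 2.64 and -0.41. A cluster of 222 nuclei led by Myh7, Nppa and Nppb stayed unnamed there, so filter and naming change together for the cardiomyocyte-like values. Reversed in the second contrast were Gdf15 in cardiomyocyte-like (0.89) and Mki67 in macrophage-like nuclei (-0.33).

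In nuclei thinned to 1000 UMIs, shares were -0.77 for cardiomyocyte-like (first contrast), 1.53 and -1.08 for fibroblast-like, -0.0083 and, reversed, -0.74 for vascular endothelial-like, and, reversed, -0.16 and -1.38 for macrophage-like nuclei. Matrix genes were at 1.58 (first), activated fibroblast genes at 2.36 and -0.19, resident macrophage genes at -0.14 and, reversed, -0.0493, the interferon response, reversed, at 0.0713 (first), the Trem2 programme at -0.17 (second) and angiogenesis at 0.30 (first). Reversed genes were Sod2 in vascular endothelial-like (-0.15) and Mmp12 (-0.23) and Mki67 (-0.54) in macrophage-like nuclei in the first contrast. In the second they were Erich1 (-0.14) and Postn (0.11) in vascular endothelial-like and Mill2 (-0.64) in macrophage-like nuclei.

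Without a filter on nuclei the fibroblast-like share was at 0.58 (first). At Leiden resolution 0.5 it was at 0.62 and -0.37, and the macrophage-like share at 0.24 (first). At resolution 2.0 the fibroblast-like share reversed to -0.53 and 0.41, because a cluster of 1304 nuclei led by Comp and Nox4 stayed unnamed. With class by marker level, shares were 0.94 and -0.55 for fibroblast-like, -0.53 and 0.27 for vascular endothelial-like, and, reversed, -0.0393 and -0.60 for macrophage-like nuclei. Activated fibroblast genes were then at 2.61 (first), resident macrophage genes at -0.16 (first), the Trem2 programme at -0.15 (second), angiogenesis at 0.36 and 0.11, and Mmp12 in macrophage-like nuclei, reversed, at 0.13 (second). With mixed clusters kept, the macrophage-like share was at 0.23 (first) and matrix genes at -0.32 (second).

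With members of at least 200 UMIs, first-contrast medians were 0.97 for cardiomyocyte stress, 1.67 for matrix, 2.66 for activated fibroblast and 0.32 for Trem2 programme genes, and -0.003, reversed, for immediate early genes in vascular endothelial-like nuclei. With no minimum of UMIs they were 1.44 for cardiomyocyte stress, 1.39 for the Trem2 programme and 1.03 for angiogenesis, and second-contrast medians of resident macrophage (-0.10) and alternative activation genes (-0.33) reversed. With TMM factors, cardiomyocyte stress genes were at -0.23 (second), sarcomere genes, reversed, at -0.002 (first), glycolysis, reversed, at 0.0367 (second), matrix genes at -0.32 (second) and resident macrophage genes at -0.55 (first). Without cluster 5, matrix genes were at 2.34 and -0.17 and activated fibroblast genes at 3.54 and -0.36. With the gene-length trend removed, activated fibroblast genes were at -0.72 (second).

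The percent of genes nearer Sham-NS, in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei, was 78.2, 79.8, 72.0 and 74.3 for genes at least 1.5-fold apart. It was 87.7 and 89.5 in the first 2 classes for genes at least 3-fold apart, and 69.6, 64.0, 55.9 and 54.3 with the other classes subtracted, over the genes measured in another class. Macrophage-like subclusters numbered 2 at resolution 0.4 and 13 at 1.2, since the resolution sets their number.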

Other observations

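The clock and position tests in this part, and the choice of the genes it names, were made after the result was seen. T cell-like nuclei made up 0.567% of Sham-NS, 1.47% of MI-NS and 0.447% of MI-DAPA nuclei, and B cell-like nuclei 0.470%, 1.40% and 0.316%. MI-DAPA had 0.308 (0.186 to 0.477) of the T cell-like and 0.231 (0.127 to 0.380) of the B cell-like share of MI-NS. A cycling cluster led by Mki67, Knl1 and Top2a, left without a class name, was at 0.579%, 1.51% and 1.58%. Pericyte-like nuclei were at 6.56%, 4.05% and 6.57%, and endocardial-like nuclei at 3.60%, 1.90% and 1.45%.

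No gene list was read in pericyte-like nuclei, and collagen RNA outside its source was higher in MI-NS. As single genes there, Col4a1 was higher in MI-NS than in Sham-NS by 1.72 (1.30 to 2.15) log2 units, Col4a2 by 1.82 (1.37 to 2.29), Fn1 by 1.96 (1.51 to 2.43) and Col5a3 by 1.82 (1.56 to 2.09). In MI-DAPA against MI-NS, Fn1 was at -1.16 (-1.61 to -0.74) and Col5a3 at 0.37 (0.18 to 0.56). In endocardial-like nuclei Nrg1, a growth factor for cardiomyocytes, was higher in MI-NS than in Sham-NS by 3.28 (2.90 to 3.69) and lower in MI-DAPA than in MI-NS, at -2.08 (-2.71 to -1.55). Edn1 followed the same course in these nuclei, at 2.81 (2.10 to 3.64) and -0.92 (-1.91 to -0.11), and the flavin monooxygenase Fmo1 was at -2.46 (-3.45 to -1.69) in MI-NS against Sham-NS.

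Clock genes differed between Sham-NS and MI-NS in every class looked at. In fibroblast-like nuclei Per2 stood at 432, 15.5 and 21.03 CPM in Sham-NS, MI-NS and MI-DAPA, while Arntl stood at 6.07, 159 and 124. A wrong scaling factor is argued against, since measurable genes driven by RRE sites, such as Arntl, went the other way. Their medians lay at least 3.02 log2 units above those of genes driven by E-boxes and D-boxes, such as Per2, in 5 classes. There were 1 to 4 measurable RRE genes per class, with Clock alone in pericyte-like nuclei. Single genes departed from this. Nr1d1, an E-box and D-box gene, was higher in MI-NS in cardiomyocyte-like (2.13, 1.85 to 2.42) and pericyte-like nuclei (1.29, 0.61 to 2.00). The RRE gene Cry1, measurable in no class, had ratios between -1.74 and -0.57. Free RNA stays open: with the library-wide profile subtracted, E-box and D-box medians were -2.28 or lower in fibroblast-, vascular endothelial-, macrophage- and pericyte-like nuclei, but the subtraction moved none of them beyond its counting interval and so tests little. Another hour of collection for Sham-NS may explain this: MI-DAPA and MI-NS differed by at most 0.30 in the E-box and D-box medians, over as few as 2 measurable genes, and RRE medians lay between -1.11, which is Clock alone in pericyte-like nuclei, and -0.04. The 2 libraries were not alike in all classes, since against Sham-NS the E-box and D-box medians were -2.20 for MI-NS and -0.99 for MI-DAPA in cardiomyocyte-like nuclei and -3.51 and -1.56 in pericyte-like nuclei. But the labels give no hour, and whether infarction alone would give such values was not tested, so hour and infarction cannot be told apart. Any other difference from Sham-NS may share the hour as its cause.

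For most genes that differ, MI-DAPA lay on the Sham-NS side of MI-NS, which was counted as nearer Sham-NS. A trend with gene length is argued against as the whole cause, since at least 75.6% of genes lay nearer Sham-NS with the trend removed. With the other classes subtracted, at least 64.0% did so in cardiomyocyte-like and fibroblast-like nuclei, among genes measured in another class. Only 50% of the genes lower in MI-NS did so in cardiomyocyte-like nuclei, and 56.6% of the genes higher in MI-NS in fibroblast-like nuclei. A shift of the same size in all classes is thus argued against as the whole cause there, though genes are not independent replicates. The subtraction does not remove a shared shift that differs in size between classes, so such a shift stays open. In macrophage-like nuclei 54.3% (47.29 to 61.16) lay nearer Sham-NS with the other classes subtracted, against 53.8% without treatment. In vascular endothelial-like nuclei 55.9% (50.98 to 60.74) did so, against 47.7%. This interval also lay above the value without treatment, though by less than in cardiomyocyte-like and fibroblast-like nuclei. In fibroblast-like nuclei the share fell too, from 87.3% as counted to 64.0%, against 52.6% without treatment. A shared shift may thus account for most of the return in macrophage-, vascular endothelial- and fibroblast-like nuclei. Dapagliflozin may lie behind the position of MI-DAPA, with at least 76.1% of genes nearer Sham-NS as counted. But a smaller infarct or another piece of tissue in the single MI-DAPA library would look alike. A deviation of the single MI-NS library would look alike too, since both parts of its nuclei carry it. So would purity of the nuclei, since the median mitochondrial share of MI-DAPA, 2.42%, lay between 3.32% in Sham-NS and 1.48% in MI-NS. The hour of collection, which the labels do not give, was not separated from treatment either. Against Sham-NS, the E-box and D-box medians of cardiomyocyte-like nuclei were -2.20 for MI-NS and -0.99 for MI-DAPA. They lay closer together in fibroblast-like (-2.70 and -2.67), vascular endothelial-like (-2.20 and -2.01) and macrophage-like nuclei (-2.83 and -2.70).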
